A study of Mus musculus with 12 samples.

How the data were processed

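The series consists of 12 dual-colour Agilent arrays of the same design. Per the labels, each array compared DNA immunoprecipitated with the M2 FLAG antibody with input DNA from neuralized mouse embryoid bodies treated with 500 nM retinoic acid and 1 µM Hedgehog agonist, after reversal of crosslinks and amplification by ligation-mediated PCR. Per the design text, 132 genes were tiled with 60-base probes at a density of 1 per 125 bases over 50 to 125 kb each, and arrays 1 and 2 of each biological replicate differ from arrays 3 and 4 in dye orientation. The labels call the replicates biological without saying how the cultures were separated, so p-values apply to these samples only.

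The deposited scanner files hold spot intensities on a linear scale. Per the file headers, they were made with Agilent Feature Extraction version 8.1.1.1 (replicates 1 and 2) or 8.1.1.18 (replicate 3), and the processed intensities were background subtracted with spatial detrending and dye-normalized with a linear factor. The scanner files also hold a deposited log10 ratio of red (Cy5) over green (Cy3), and the authors' value table holds the same log10 ratio for each array to within 0.005, with no centring and with the dye-swapped arrays left in the opposite sign. Its medians per array lay close to 0. Flags for outliers, saturation and signal over background were taken from the same files. The median raw intensity per array was 252 to 371 in the ChIP channel and 302 to 404 in the input channel, over a median background of 32.0 to 50.0 and 33.0 to 49.0.

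The main measure was log2 of the ChIP over the input processed intensity. The ChIP channel was taken from the dyes in the labels, and arrays with ChIP in Cy3 had their sign turned. Spots flagged as outliers were set to missing, the 1384 control spots were left out, and each array was centred on its median without loess or quantile normalization. The 4 arrays of each biological replicate share the same material and were averaged to 1 value, giving n = 3. The description and the source name of 1 array give different biological replicates. The description was followed, which puts the array in replicate 3, and the other choices were tried as alternatives. With this choice, arrays of the same replicate and dye orientation, this array among them, correlated at 0.921 or more across probes. Arrays of different replicates correlated at 0.223 or less, which argues against the replicate in the source name. Scan sessions held replicates 1 and 2 together and replicate 3 apart. A model with the session as a random block could not be fitted on 3 values, and the value within the first session is that without replicate 3.

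Windows were the mean of all probes centred within 300 bp of a probe, with at least 4 probes, and were tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment over all windows. With 3 values per window, limma borrows variance across windows, and the total degrees of freedom were 17.3. The p-values therefore do not rest on the spread between a window's own replicates alone, which is given as the SD. An enriched region was a run of at least 3 windows with an adjusted p under 0.05 and a mean log2 ratio of at least 0.585 (1.5-fold), joined up to 500 bp apart, and the mirrored rule counted regions with ChIP below input. Single probes were tested the same way. Tiles were runs of probes with gaps of at most 10000 bp. Regions were named by a fixed rule: the 25 with the highest peak among those above 0 in each replicate, which took in all 20. The site search used Biostrings 2.70.1 on the genomic part of each probe, because 22133 probes are filled up to 60 bases with a shared linker of up to 15 bases. Control windows, 10 per region, were drawn with a fixed seed from tested windows of the same tile that held no called window. The dye test used, per replicate, the mean of the Cy5-ChIP arrays minus that of the Cy3-ChIP arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

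The calling was tested on simulated data: replicates were shifted against one another along the array, the real regions were taken out, and 50 triangular stretches of each of 4 heights were added. For the enriched regions, over 33126 windows, 12% of stretches with a peak log2 height of 1 were recovered, 58% at 1.5, 90% at 2 and 96% at 3. These heights are at the apex of a stretch, while region peaks are means over windows of 300 bp on each side. A stretch adds less to its window mean than its height, so these shares cannot be set directly against region peaks. Each stretch also had the same height in every replicate, so the shares do not cover enrichment that differs between replicates. No region was called away from an added stretch above input, and 1 was called below input. So many added stretches make the adjusted p more lenient than in the real data.

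Positions are given as the array design gives them. Their genome build is not given in the sources used here, and the files pair probes with positions and sequences but not with gene names, so no gene is named. For this reason the planned tests of 7 gene lists and of the distance to transcription start sites were not run. Of the array's probes, 179 lie on unplaced sequence. Alternatives covered the background correction, normalization, source of the ratio, filters on dim and saturated probes, window size, thresholds, run length, single replicates left out, technical arrays, dye orientation, the array with the conflicting label and probe GC content. These tests, alternatives and the naming rule were fixed before the data were examined, except where stated.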

Results

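Chromatin from mouse embryoid bodies was profiled on a custom genomic tiling array after immunoprecipitation with the M2 antibody against the FLAG epitope. Embryoid bodies are aggregates of differentiating embryonic stem cells; these had been driven to a neural fate and treated with 500 nM retinoic acid and 1 µM of a Hedgehog agonist. The series title gives the purpose as finding targets of an activator form of Gli, the transcription factor family at the end of the Hedgehog pathway, in the ventral neural tube. Each array compared the immunoprecipitated DNA (ChIP) with sheared chromatin that had not been precipitated (input). There were 12 arrays from 3 biological replicates, with 4 arrays per replicate and the dyes exchanged on 2 of them. The array carried 42850 tiling probes in 167 tiles, which spanned 7736 kb on 19 chromosomes with a median spacing of 119 bp. Between 96.5% and 99.3% of the probes were well above background in the input channel of an array, and between 94.0% and 99.2% in the ChIP channel. The design holds 1 condition, so the comparison is ChIP against input, and the number of biological replicates limits its precision. None of the arrays held a precipitation from cells without the tag or with a control antibody, and the labels do not name the tagged protein. Enrichment over input can therefore not be told apart from non-specific precipitation by the antibody.

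Enrichment over input was found at 20 regions, and no region lay below input by the mirrored rule. Of 23 alternative settings, 10 gave between 1 and 19 regions below input. The 19 came from a fit of all 12 arrays, in which arrays that share material count toward the degrees of freedom. The highest count otherwise was 5, without replicate 1. The regions fell in 11 of the 165 tiles with a testable window, on 7 chromosomes, and together covered 11124 bp. The mean log2 ratio of ChIP over input at their peaks ranged from 1.52 to 3.18, which is 2.87-fold to 9.03-fold, and 8 regions reached at least 4-fold. The lower end depended on the background correction, since with raw signals the peaks ranged from 0.68 to 2.90. Every one of the 20 peaks was above 0 on all 12 arrays, but the regions were called on these same arrays, so this is not independent evidence. The regions were short, with a median span of 472 bp and a range of 221 to 1370 bp. Of the 34082 windows tested with limma, 120 were above input and 3 below it at an adjusted p under 0.05, against 1662 above and 1187 below at an unadjusted p under 0.05. The count of regions was lowest without replicate 3, at 6, against 17 and 24 without replicates 1 and 2. Each of these fits had 2 values per window, so its count also depends on the variance that limma borrows across windows. Between 12 and 58 regions were called from the arrays of a single dye orientation.

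**Figure D1:**
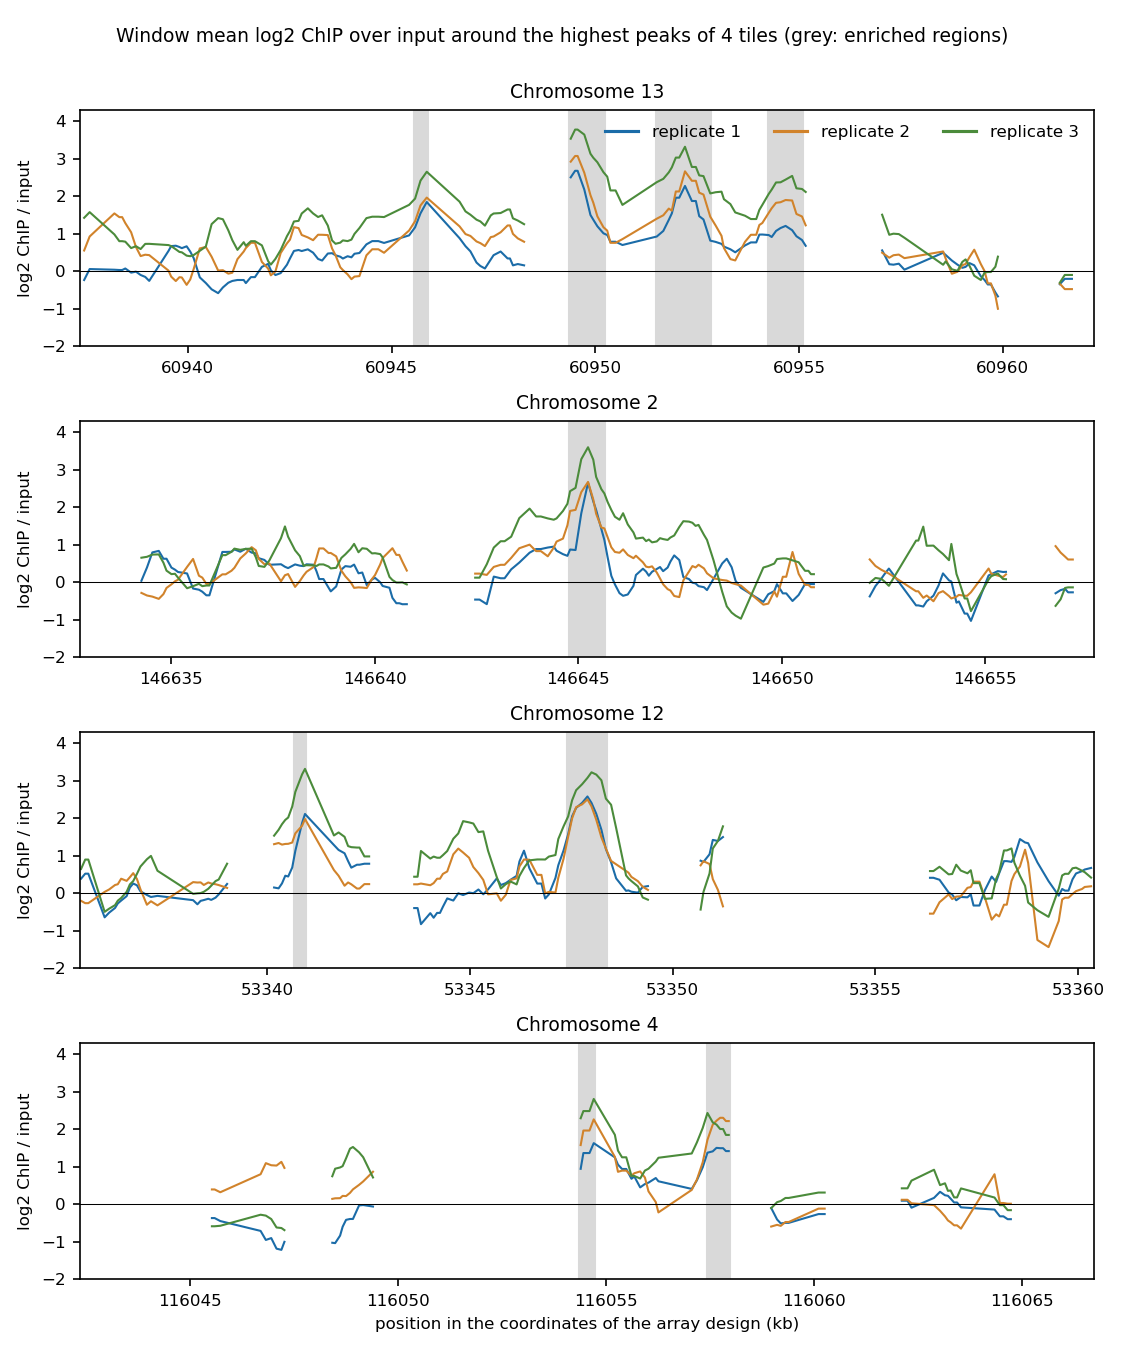
Window mean log2 ChIP over input (vertical axis) against position in the coordinates of the array design in kb (horizontal axis) around the highest peak of 4 tiles, with 1 line per biological replicate and enriched regions in grey. Lines break where windows held too few probes; the highest peaks are on chromosome 13 (mean 3.18), chromosome 2 (2.98), chromosome 12 (2.72) and chromosome 4 (2.23), and in each of these regions all 3 replicates lie above 0.

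The strongest enrichment was on chromosome 13, where 1 tile (60869580 to 61023387) held 5 separate regions. The highest of them, at 60949367 to 60950230, had a peak log2 ratio of 3.18 ± 0.56 (SD, n = 3), with 2.68, 3.07 and 3.78 in replicates 1, 2 and 3 (limma adjusted p = 6.93e-05). Its neighbour at 60951481 to 60952851, the longest region on the array, reached 2.75 ± 0.53. The regions starting at 60945548 and 60954226 reached 2.15 ± 0.44 and 1.85 ± 0.62. Between these 4 regions, whose neighbours lie 1251 to 3473 bp apart, the lowest window mean was 0.65, so the ratio fell between peaks without returning to 0. The region furthest to the right, at 61010340 to 61010580, was 55239 bp away and peaked at 1.61 ± 0.46, and the lowest window between it and its neighbour was at −0.59.

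On chromosome 12, a tile from 53197585 to 53497856 held 3 regions. Those starting at 53347396 and 53340665 lay 6440 bp apart and reached 2.72 ± 0.31 (adjusted p = 0.000131) and 2.47 ± 0.74 (adjusted p = 0.000606). The region starting at 53245721, 94289 bp to the left, reached 1.99 ± 0.44. Chromosome 2 carried single regions in separate tiles. The one at 146644771 to 146645666 had the second highest peak of all, at 2.98 ± 0.54 (adjusted p = 8.61e-05), and the one at 147493674 to 147494413 reached 1.84 ± 0.29. The difference of these peaks was larger than the spread of either.

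A pair of regions on chromosome 4, at 116054355 to 116054723 and 116057412 to 116057972, peaked at 2.23 ± 0.59 and 1.95 ± 0.39, a difference within the spread between replicates. The lowest window between them was at 0.54. A single region at 127076781 to 127077445 on chromosome 10 reached 2.22 ± 0.80 and differed between replicates from 1.33 in replicate 1 to 2.88 in replicate 3. On chromosome 8, neighbouring regions starting at 79268480 and 79270062 reached 1.64 ± 0.80 and 1.75 ± 0.69, with a lowest window of 0.27 between them.

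The remaining 5 regions peaked at 1.52 to 1.71. The region at 84215193 to 84215414 on chromosome 8 had the widest spread, with log2 ratios of 1.79, 2.51 and 0.53 in replicates 1, 2 and 3 and an adjusted p of 0.0463. It was called again without replicate 3 and was lost without replicate 1 or replicate 2. On chromosome 10, regions starting at 102925919 and 102963783 peaked at 1.71 ± 0.61 and 1.54 ± 0.49. The region starting at 30577610 on chromosome 12 peaked at 1.60 ± 0.22, and that starting at 52789590 on the X chromosome at 1.52 ± 0.72. The region starting at 30577610 had the smallest spread of the 20 but was not called with any 1 of the 3 replicates left out. Its peak was then at 1.73, 1.54 and 1.54 without replicates 1, 2 and 3, and the peak window passed without replicate 1 or replicate 2. These last 4 regions had input signals below the median of their tile, by 1.40, 0.08, 0.80 and 0.39 on the log2 scale in that order, and were not called again with the trend on probe GC content removed, when their peaks were at 1.46, 1.46, 1.48 and 1.42. In the same order their peaks were at 0.68, 0.83, 0.91 and 0.80 with raw signals and at 0.85, 1.00, 1.05 and 0.97 after normexp background correction. With probes not well above background in the input left out, the region starting at 102925919 had no testable window at its peak. The others were then at 1.41, 1.48 and 1.20, and the peak on the X chromosome did not pass. The regions starting at 60945548 on chromosome 13 and 79268480 on chromosome 8 were also not called again, with peaks that moved from 2.15 to 2.05 and from 1.64 to 1.53. All 6 then had fewer than the 3 called windows a region needs.

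**Figure D2:**
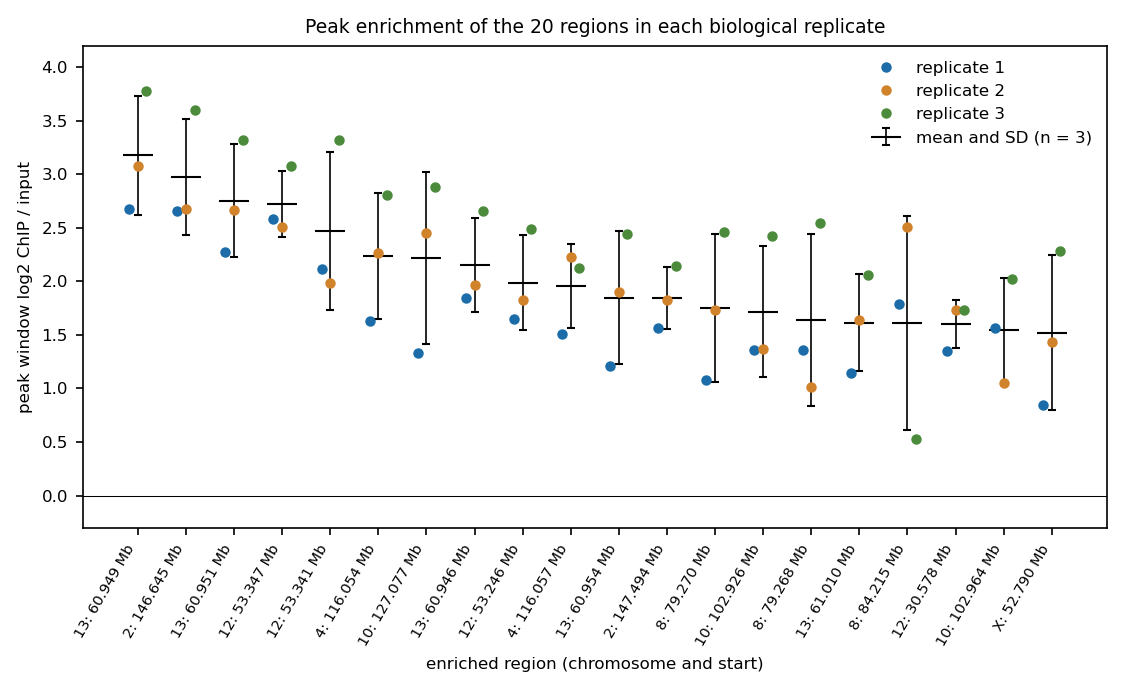
Log2 ChIP over input at the peak window (vertical axis) of the 20 enriched regions (horizontal axis, named by chromosome and start), with 1 point per biological replicate and the mean and SD of the 3 replicates in black. All points lie above 0; replicate 3 is highest at 18 regions, and at the region on chromosome 8 starting at 84215193 it is the lowest (0.53).

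The peaks were higher in replicate 3, whose mean over the 20 peaks was 2.53, than in replicates 1 and 2, at 1.68 and 1.99. Replicate 3 had the highest value at 18 regions and replicate 2 at the other two. The ratios of replicate 3 were also more spread over probes outside the regions, with an SD of 0.93 against 0.74 and 0.81 in replicates 1 and 2. Regions chosen on the mean over replicates can favour the replicate with the widest spread, but whether this accounts for the higher peaks was not tested. Replicate 3 was scanned in a separate session from replicates 1 and 2, so the session and the replicate cannot be told apart.

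Both channels were bright at most regions. Relative to the median window of the same tile, the ChIP channel at the peaks was higher by a median of 2.72 on the log2 scale, and the input channel by a median of 0.90. The input lay above its tile median at 14 of the 20 regions and reached 2.00 above it at the region starting at 53340665 on chromosome 12. At the region starting at 102925919 on chromosome 10, the ChIP channel was 0.05 above its tile median and the input channel 1.40 below it. Against the tile median, a weak input signal cannot be told apart from probes that are dim in both channels.

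**Figure D3:**
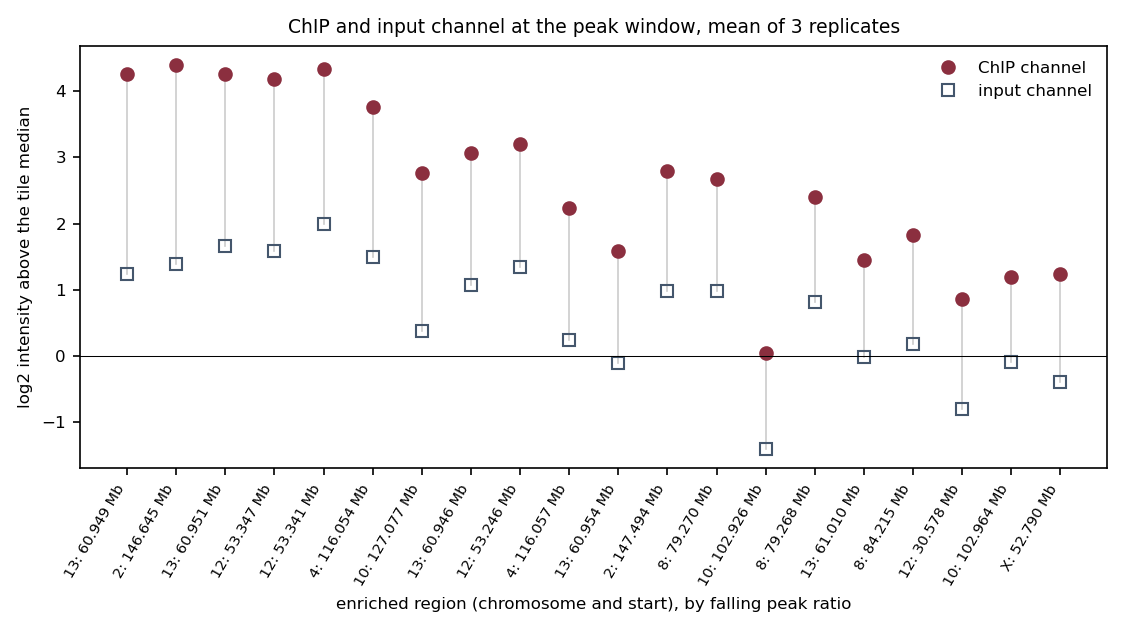
Log2 intensity at the peak window above the median window of the same tile (vertical axis), for the ChIP channel (filled circles) and the input channel (open squares), as the mean of 3 biological replicates at each of the 20 enriched regions (horizontal axis, in order of falling peak ratio). The input is above the tile median at 14 regions, and at the region on chromosome 10 starting at 102925919 it lies 1.40 below it.

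No single probe passed the threshold. Among 42850 probes, limma gave 0 with an adjusted p under 0.05 in either direction and a smallest adjusted p of 0.374, while 1782 were above and 1432 below input at an unadjusted p under 0.05.

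Across the array as a whole, the biological replicates had little in common. Across 34082 windows, which overlap and are not independent, Pearson's r between replicates was 0.110 (replicates 1 and 2), 0.144 (1 and 3) and 0.124 (2 and 3), and Spearman's rho was 0.0913, 0.115 and 0.0791. With the regions and 1000 bp on each side left out, r was 0.0724, 0.104 and 0.0732. Arrays of the same biological replicate were far closer, with r across probes of 0.921 to 0.973 in the same dye orientation and, turned to ChIP over input, of 0.674 to 0.908 between dye orientations. Using pairs of replicates alone, 17 regions were called from replicates 2 and 3, 24 from replicates 1 and 3, and 6 from replicates 1 and 2. With 2 values per window these calls lean on the variance that limma borrows across windows. The total degrees of freedom were 31.4, 91.1 and 16.5 in that order, so the counts do not measure agreement alone.

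The consensus Gli site, TGGGTGGTC, was searched on both strands in the genomic part of the probes, which covers 30.45% of the tiled bases. It was present in 1 of the 20 regions (5.0%) and in 1 of 200 uncalled windows of the same length in the same tiles (0.5%), a difference that did not pass the test (two-sided Fisher exact p = 0.174). With 1 region holding the site the test could not pass, since p was still 0.0909 where 0 of 200 control windows held it. It therefore cannot decide whether the exact site is enriched. The region with the site was the one on chromosome 4 at 116057412 to 116057972, where the probe at 116057537 to 116057586 holds it. The array held the exact site on 10 probes, of which 6 had a testable window and 1 lay in a region. Allowing 1 mismatch, 3 of 20 regions, the one with the exact site among them, and 3 of 200 control windows (1.5%) had a match (Fisher p = 0.0109). With 100 other draws of the control windows the p ranged from 0.00245 to 0.144 and was under 0.05 in 71. A mean of 2.74% of control windows had a match in these draws. Control windows of a tile can overlap, and 14 of the 20 regions share a tile with another, so the test treats as independent counts that are not. The regions offered more searched sequence than the controls, at a mean of 307.8 and 230.0 bases.

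The ratio depended on the dye at 363 of 34077 windows (limma, adjusted p under 0.05), of which 348 were higher with the ChIP sample in Cy5 and 15 with it in Cy3. At an unadjusted p under 0.05 the balance was the other way, with 5725 higher with the ChIP sample in Cy5 and 6874 with it in Cy3. At the region peaks the difference between orientations ranged from −0.16 to 0.50 on the log2 scale, with a median of −0.08. It passed the threshold at 1 of the 20 peaks, the region on the X chromosome, where the ratio was higher by 0.43 with the ChIP sample in Cy5 (adjusted p = 0.0392). The regions starting at 102925919 and 102963783 on chromosome 10 and at 30577610 on chromosome 12 were higher by 0.50, 0.45 and 0.33 in the same direction without passing, and these and the X region were among the 8 not called from the Cy3-ChIP arrays alone. The other 16 peaks lay between −0.16 and 0.01. Each replicate held both orientations equally, so a dye effect that adds a constant to the log2 ratio of red over green cancels in its mean. Whether the difference at these regions is of that kind was not tested.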

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

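Against 20 enriched regions, 31 were called after normexp background correction (19 of the 20 among them) and 32 after loess (all 20 among them). Fewer were called under narrower or stricter settings: 5 with windows of 150 bp on each side, 10 at an adjusted p threshold of 0.01, and 9 with runs of at least 5 windows, all of them among the 20. The Cy3-ChIP arrays alone gave 12, also all among the 20, while the Cy5-ChIP arrays alone gave 58 regions, with all 20 among them, and 2 below input. Without 1 replicate the count ranged from 6 to 24; without replicate 1 there were 17 above and 5 below input, and without replicate 2 there were 24 above and 3 below. A fit of all 12 arrays with the biological replicate as a random block gave 63 regions above input (16 of the 20 among them), 19 below, and 751 single probes against 0. This fit takes its degrees of freedom from 12 arrays, although arrays of a replicate share the same material. Its counts can therefore be too high and are not evidence from more than 3 replicates. The other settings with a test gave between 15 and 30 regions and, where probes were tested, 0 probes; the fold thresholds changed no call. Below input there was 1 region after normexp, from the deposited ratio, from the value table and with dim probes left out, and there were 2 with runs of 1 window and with the conflicting array in replicate 1. A count without a test, chosen after seeing the data, found 17 regions above a log2 ratio of 1 in each replicate and 0 below −1. The 4 highest peaks were called under all 23 alternatives. The share of regions with the Gli site passed the test with 1 mismatch allowed (15% of regions), but not in 29 of 100 other draws of the controls, chosen after seeing the data. No alternative with the exact site passed, but with at most 1 region holding it none could. The lowest Fisher p for the exact site over 100 draws of the controls was 0.0909. The mean correlation of biological replicates was 0.126, with 0.0779 for single probes and 0.0832 with the regions and 1000 bp on each side left out. The 363 windows that depended on the dye became 0 after loess, which removes a dye trend by construction, and 10754 after normexp. For the rest, the cause was not tested. The planned gene list and start site tests were not run. Of the probes, 2388 were not well above background in the input on 1 or more arrays; without them 17 regions were called above input, with 16 of the 20 among them. The peaks of the 20 regions ranged from 0.68 to 3.42 over the settings that gave them a value and stayed above 0 in each of these.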

Other observations

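The tests in this part were chosen after the regions were seen, except those of the Gli site and of the calls with the GC trend removed. The array design gave some loci far longer tiles than others, and most regions lay there: 16 of the 20 regions were in tiles over 100 kb, which hold 28.6% of the tested windows. This is a description and was not tested. The reason for the tile lengths is not given in the sources used here. Regions also lay in groups, with 14 of the 20 in 5 tiles that held at least 2. Among 160 tiles with at least 20 probes, the mean log2 ratio ranged from −0.28 to 0.30, and limma gave 0 at an adjusted p under 0.05, with 20 above and 22 below 0 at an unadjusted p under 0.05, where chance alone gives about 8 in all.

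No short sequence word passed a test in the probes of the regions. Of 8192 words of 7 bases, counted with their reverse complements in the 110 probes of the regions against all other probes, 0 passed a hypergeometric test after Benjamini-Hochberg adjustment, and the smallest adjusted p was 0.553. Of the 279 probes with the Gli site at up to 1 mismatch, 3 lay in a region, and the median window mean at such probes was 0.00, close to the −0.01 of all windows.

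The enrichment in 1 direction was set against noise and probe properties. Shifting the replicates against one another along the tiled probes gave as many as 20 regions in 0 of 100 shifts, and the highest count was 0, which argues against noise falling on the same place. Turning the sign of replicates makes 4 splits, too few for a share under 0.05; the real one gave 20 regions and the highest other 0, with 1 split as large. A weak input signal is argued against for most regions, because the excess of the ChIP channel over its tile median was a median of 144% of the difference between the ChIP and input excesses. It gave under 50% at 1 region, on chromosome 10. The share was 52.0% at the region starting at 30577610 on chromosome 12 and 76.3% at the region on the X chromosome. The input lay below its tile median at each of these, so a weak input stays open there. Removing the trend on GC content lowered the peaks by a median of 1.40% and at most 15.1%, so GC content does not account for their height, yet 14 regions were called again and 6 were not (mean peak 1.70 before and 1.56 after, with mean SDs of 0.55 and 0.57): the peak window of 3 of these still passed, but each kept at most 2 called windows.

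Ratios outside the regions recurred between arrays of 1 biological replicate but hardly between replicates. GC content explained at most 4.83% of their variance in a replicate, and spots next to each other on the slide correlated at −0.0029, so neither GC content nor slide position accounts for the pattern; other features of the probes were not tested. Within a replicate, probes 60 to 200 bp apart correlated at 0.518, probes 200 to 400 bp apart at 0.182 and probes 1000 to 2000 bp apart at 0.0386. A candidate explanation is that few chromatin fragments were recovered before amplification, so that each replicate carries its own random set of amplified fragments. The input channel correlated between replicates at 0.919 to 0.958 and the ChIP channel at 0.706 to 0.762, and a difference in binding between cultures stays open, as no biological explanation was tested.

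The input channel was also bright at the regions, by a median of 0.90 on the log2 scale over the tile median, a level that 11.4% of other windows exceeded; the median was 1.37 at the 10 highest peaks and −0.05 at the 10 lowest, so the excess was mostly in the stronger regions. GC content predicted 2.43% of this excess, which argues against GC content. The excess was nearly equal with the input in either dye (99.5% of the higher), which argues against crosstalk that is stronger from 1 dye than from the other. Crosstalk of equal strength in both directions would give the same result and stays open. Within the regions the input of a replicate went up with its ChIP signal with a slope of 0.386, above 95% of 1000 random sets of as many windows (median 0.226, upper bound 0.335). The random sets were not matched on brightness, and the regions had been chosen for a ratio that held across replicates. The slope therefore cannot show whether some precipitated DNA reached the input material. If some did, the ratios of the stronger regions may understate their enrichment. A preference of the input itself for these places, such as open chromatin, stays open and was not tested.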
